A study of Homo sapiens with 6 samples.

How the data were processed

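Polyadenylated RNA of MDA-MB-231 cells, an invasive, mesenchymal-like triple-negative breast cancer line, was sequenced in 6 libraries. Per the labels' protocols, the cells carried a stably integrated lentiviral vector after puromycin selection, either the control vector (shControl, 3 libraries) or the same vector with a short hairpin RNA against NSD3 (shNSD3, 3 libraries). RNA was extracted with TRIzol and the libraries were made with a stranded Illumina TruSeq mRNA kit, per the labels' protocols. NSD3 encodes a histone H3 lysine 36 methyltransferase and appears in the deposited table under its older symbol WHSC1L1. NSD2 appears there as WHSC1.

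The deposited values were raw counts per gene, whole numbers for 26364 gene symbols in 6 columns. The submitters' processing notes name bcl2fastq, STAR 2.6.0c, featureCounts of Subread 1.6.2 and the genome build hg19. The annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes with a near-identical copy (MAGEA6 and MAGEA3, HSPA1B and HSPA1A, the HLA-DRB genes) and genes that overlap another one are therefore uncertain, since reads could be split between copies or dropped. The mitochondrially encoded mRNAs of a prepared list were not analysed here, because none of its 13 symbols matched a symbol of the table. Total counts ranged from 28315487 to 33117357 per library, so that 1 count equalled 0.0302 to 0.0353 CPM, the count scaled to library size.

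Libraries were assigned to groups by their sample titles. The design text calls the 3 samples of a group biological replicates and does not say whether they came from separate infections. The p-values therefore measure the spread between these samples, which may be that of parallel cultures of a single infected population per group, and a difference between the groups can also hold differences between the infected populations. The sources name 1 hairpin only. Pairs of libraries were compared by a chi-square test over genes with at least 10 summed counts. Within groups the statistic per degree of freedom was between 1.41 and 4.21, above sampling noise in every pair, so all 6 libraries were counted separately.

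Differential expression was tested in R 4.3.3 with edgeR 4.0.16 on the counts as deposited, with TMM normalisation, the default expression filter (filterByExpr, which kept 14987 genes), robust quasi-likelihood fits and two-sided quasi-likelihood F tests of shNSD3 against shControl. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and genes with an adjusted p under 0.05 were called. Log2 fold changes are shNSD3 over shControl, given with their standard error (SE), and CPM values use the TMM library sizes, given as mean ± SD of 3 libraries. The SE was taken as the absolute log2 fold change over the square root of the F statistic. It can understate the error of large changes in genes with few counts in a group. On simulated counts for this comparison (14936 genes, 50 changed at each size), the fit recovered 54% of genes changed by 0.25 on the log2 scale, 74% at 0.5, 82% at 1 and 100% at 2, with 9 false calls. The simulation changed far fewer genes than the 59.1% called in the data, which makes the adjusted threshold stricter. These rates therefore do not carry over to the real comparison. For a gene at 0 counts in a group, the fold is a lower bound against a floor of 3 counts over the group. Bounds of this kind cover counting error only.

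A total of 25 gene lists were written before the data were examined, together with the test, the alternatives and the rule for named genes. Of these lists, 24 had tested members. Each was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, which asks whether a list moved relative to the other genes, with Benjamini-Hochberg adjustment over the lists. The test was repeated with a correlation estimated from the residuals and with fry, which asks whether a list's genes moved on balance in a single direction. The estimated correlation was below the preset for some lists, so a call lost with it need not reflect correlated members. Member counts are given over all genes tested and adjusted over the list alone. Genes named in the text are NSD3, NSD1, NSD2, NOTCH1, NOTCH2, NOTCH3, JAG1, JAG2 and HES1, the 6 higher and 6 lower called genes with the largest log2 fold change among those with a mean of at least 5 CPM and no overlap between the groups, and from each list up to 2 members with the largest change in its more frequent direction and 1 in the other, with a mean of at least 1 CPM. The lists of leukocyte, endothelial and stromal, histone and mitochondrial genes were exempt from the last part. Members outside the rule are named where a count of 5 or fewer is spelled out, and other exceptions are stated. Some genes that the rule selects are not reported here.

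The order of genes along chromosomes was taken from a RefSeq gene table of assembly GRCh38.p14, matched by symbol for 13740 tested genes and by older symbol for 948. No coordinates are given, since that assembly differs from the build of the counts. Blocks of 20 neighbouring genes with a mean of at least 5 CPM were summarised by their median log2 fold change. This step was chosen after seeing the data, as was positional centring, in which the median of the 40 nearest such genes (20 on each side where the chromosome allows) was subtracted from each log2 fold change and lists were tested with cameraPR. Tests after centring used each gene's own SE and took that median as known, so their p-values leave out its error. The genes beyond the ends of the list flanking NSD3 were also chosen after seeing the data. GC content and transcript length came from the longest GENCODE transcript per gene on GRCh38.

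Alternatives fixed before the data were examined were DESeq2 size factors, upper-quartile factors and library totals in place of TMM, no low-count filter, a filter at 1 CPM in all libraries of a group, a fit without the robust option, DESeq2 1.42.0, limma-voom, the replicate number as a block, and leaving out each library in turn.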

Results

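The data set held 6 RNA-seq libraries of MDA-MB-231 cells, 3 from cells carrying the control vector (shControl) and 3 from cells carrying a hairpin against NSD3 (shNSD3). Total counts were 31139119, 30273624 and 33117357 in the shControl libraries and 30367567, 28315487 and 29328711 in the shNSD3 libraries. The comparison of the groups asked which transcripts differ when NSD3, an H3K36 methyltransferase gene of the 8p11 region that is often amplified in breast cancer, is depleted, with Notch signalling as an interest of the study. The first principal component of log CPM values held 79.1% of the variance and separated the groups. On the second component (6.37%) shControl replicate 2 lay at -16.3, apart from the other shControl libraries (8.83 and 8.39).

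NSD3 mRNA was lower in every shNSD3 library. Its level was 93.1, 90.0 and 86.6 CPM in the shControl libraries and 18.8, 19.97 and 19.0 CPM in the shNSD3 libraries, or 89.9 ± 3.24 against 19.3 ± 0.621 CPM (SD, n = 3 each). NSD3 fell by 2.22 ± 0.05 (SE) on the log2 scale, so that 21.4% of the control level remained (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.68e-31). Of its closest relatives, NSD1 fell slightly, with a log2 fold change of -0.12 ± 0.03 (edgeR adjusted p = 0.00231), which was close to the median of its 40 chromosomal neighbours (-0.13) and was not called with library totals in place of TMM. NSD2 did not pass the test (-0.06 ± 0.03, edgeR adjusted p = 0.102). It was called lower without shControl replicate 2 (-0.06, adjusted p = 0.0391) and with positional centring (-0.14, adjusted p = 2.18e-04). The centred p-value leaves out the error of the neighbours' median.

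**Figure D1:**
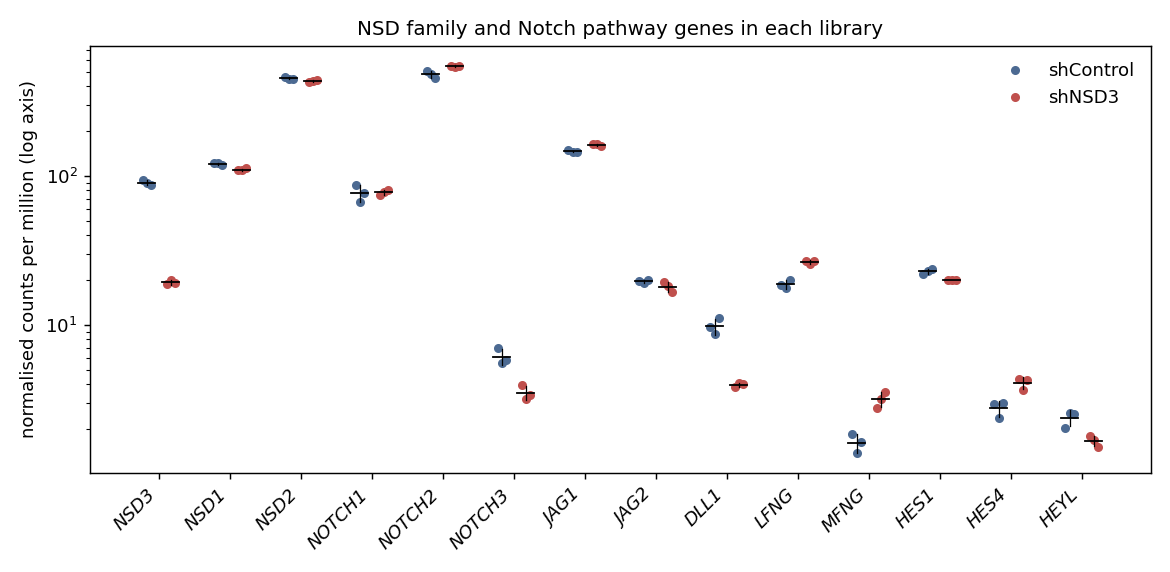
Normalised CPM (log axis) of NSD family and Notch pathway genes in the 3 shControl (blue) and 3 shNSD3 (red) libraries, each point a library, horizontal bars the mean and vertical bars 1 SD. NSD3 lay at 89.9 CPM in shControl and 19.3 CPM in shNSD3 on average, while NOTCH1 (76.8 and 77.4 CPM) overlapped between the groups.

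Many genes differed, most of them by little. Of 14987 genes tested, 8861 (59.1%) were called, 4366 higher and 4495 lower in shNSD3, and the median absolute log2 fold change of called genes was 0.31. Among called genes, 80.2% changed by less than 1.5-fold. Counts of called list members below are to be read against the 59.1% called over all genes. A change of at least 2-fold was seen for 648 genes, 397 higher and 251 lower. The groups did not overlap for 63.3% of tested genes, against 10% by chance. The share of higher genes among those called was 49.3% with TMM and 65.1% with library totals, and the number changed at least 2-fold was 394 with the filter at 1 CPM.

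Among genes with a mean of at least 5 CPM and no overlap between the groups, those that rose most were MIR30A, PASD1, MAGEA6, TRPM3, IL32 and MAGEA11. MIR30A, a microRNA gene, had 0 counts in shControl and 853 ± 26.6 CPM in shNSD3 (SD, n = 3), at least 26100-fold higher, while the neighbouring LINC00472 was at 50.1 and 52.3 CPM (log2 fold change 0.06 ± 0.04). The MIR30A reads may come from the hairpin vector and not from the gene, as weighed in the other observations below. PASD1, an X-linked cancer-testis gene, also had 0 counts in shControl and reached 15.5 ± 0.741 CPM, at least 474-fold higher. The melanoma antigen genes MAGEA6 and MAGEA11 rose by 9.08 ± 0.16 and 3.54 ± 0.13 (log2, SE). MAGEA6 shares nearly all its sequence with MAGEA3 and had 6 counts over the shControl libraries, so few that its SE understates its error. TRPM3, an ion channel gene, rose from 0.110 to 11.6 CPM, and the cytokine gene IL32 rose 12.2-fold, from 2.61 ± 0.494 to 32.0 ± 0.613 CPM.

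Under the same limits, the genes that fell most were STARD8, CNTNAP2, GPC6, BMP5, ANKRD30A and NSD3 itself. STARD8 fell from 144 ± 6.07 to 17.2 ± 1.05 CPM, 8.35-fold lower (edgeR adjusted p = 5.27e-36). CNTNAP2, a neurexin family gene, fell by 3.00 ± 0.10 and the glypican gene GPC6 by 2.32 ± 0.10 (log2, SE). BMP5, a bone morphogenetic protein gene, was 4.96-fold lower and the breast differentiation antigen gene ANKRD30A 4.76-fold lower.

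Notch pathway genes moved in both directions, as did tested genes in general, of which 59.1% were called. Of 30 receptors, ligands and signalling components, 12 rose, 6 fell and 12 did not pass the test, with the same counts adjusted over the list alone. NOTCH3 was 1.74-fold lower (6.12 ± 0.763 against 3.51 ± 0.384 CPM, edgeR adjusted p = 1.1e-07), and the ligand gene DLL1 fell 2.48-fold. NOTCH2 and JAG1 rose slightly, by 0.18 ± 0.03 and 0.14 ± 0.03 (log2, SE), where the neighbours of JAG1 had a median of 0.07 and its call was lost with positional centring (adjusted p = 0.0585). MFNG and LFNG, glycosyltransferase genes that modify Notch receptors, rose 1.94-fold and 1.41-fold, MFNG from a low level (1.62 to 3.16 CPM). NOTCH1 (0.01 ± 0.09) and JAG2 (-0.12 ± 0.06) were not called. JAG2 was called lower without shControl replicate 2 (-0.14, adjusted p = 0.0484) and without shNSD3 replicate 1 (-0.17, adjusted p = 0.0349). With positional centring JAG2 was also called lower (-0.28, adjusted p = 2.04e-04), where the p-value leaves out the error of the neighbours' median. The list as a whole did not pass camera (adjusted p = 0.629, direction up, median log2 fold change 0.04, mean -0.005) but did pass fry (adjusted p = 0.0189).

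Of 13 Notch target genes, 4 rose and 5 fell, also adjusted over the list alone. HES4 rose 1.48-fold, whereas HES1 (-0.20 ± 0.06), HEYL (-0.51 ± 0.16, with neighbours at -0.24) and IGF1R (-0.24 ± 0.04, with neighbours at -0.22) fell (log2, SE). HEYL was at 2.38 CPM or less in both groups, and HES1 was not called with library totals. With positional centring the log2 fold changes of HES1, HEYL and IGF1R were -0.12, -0.27 and -0.02 and none was called (adjusted p = 0.0622, 0.154 and 0.719). The list did not pass camera (adjusted p = 0.992, direction up, but down with upper-quartile factors or library totals), and its median of -0.03 and mean of -0.14 had the opposite sign.

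Genes flanking NSD3 on 8p fell together. Of 17 tested, 13 fell and 0 rose, with the same counts adjusted over the list alone and a median log2 fold change of -0.29 (camera adjusted p = 8.57e-04, or adjusted p = 0.0939 with an estimated correlation). EIF4EBP1, a translation repressor gene, fell by 0.59 ± 0.05 (log2, SE) and BRF2, an RNA polymerase III factor gene, fell 1.43-fold. The 40 nearest genes with at least 5 CPM beyond the ends of the list, 20 on each side, also had a median below 0 (-0.17, SD 0.218, 23 called lower and 3 higher). Blocks of 20 genes were lower over a longer run of chromosome 8, from LOXL2 to PAG1. The first and last blocks of that run had medians of -0.341 and -0.395, and the block from TTI2 to TM2D2, with list members, -0.29. The blocks before and after the run were at 0.004 and 0.007. The fall was thus not centred on NSD3. Positional centring ended the call (adjusted p = 0.583), which decides nothing here, since the subtracted medians include list members. Among 13 other H3K36 methyltransferase and demethylase genes, 1 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.656, fry adjusted p = 2.66e-04). SMYD2 fell by 0.40 ± 0.04 and KDM4A by 0.30 ± 0.04, while KDM2A rose by 0.39 ± 0.03 (log2, SE) in a region where neighbouring genes had a median of 0.42. For KDM4A that median was -0.23.

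Among mesenchymal and invasion genes, the matrix gene SPARC fell 2.47-fold, from 293 ± 6.30 to 118 ± 1.90 CPM, and WNT5A fell 1.94-fold. PDGFRB, a growth factor receptor gene, rose 1.95-fold. Of 22 genes 6 rose and 10 fell, also adjusted over the list alone, with a median of -0.01 and a mean of -0.12 (camera adjusted p = 0.0159, or adjusted p = 0.143 with an estimated correlation). The call was also lost without the low-count filter (0.114), with limma-voom before camera (0.317), and with cameraPR, both without (0.302) and with positional centring (0.996). Epithelial genes were mixed, 8 higher and 7 lower of 23, also adjusted over the list alone (camera adjusted p = 0.629). The epithelial transcription factor genes ELF3 and EHF rose 5.91-fold and 3.89-fold, to 21.1 and 4.49 CPM, and the splicing factor gene ESRP1 fell 2.45-fold. Of 25 matrix metalloproteinase and collagen genes, 13 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.866). MMP3 rose 3.47-fold, from a low level (1.29 to 4.43 CPM), and COL1A1 1.43-fold. THBS1, among the most abundant transcripts of the list, fell from 5658 ± 200 to 3085 ± 56.2 CPM.

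Markers of breast lineages also split. Of 12 luminal genes 2 rose and 7 fell (camera adjusted p = 0.0502, or adjusted p = 0.466 with an estimated correlation). Those that fell included FOXA1 (2.52-fold lower) and CA12 (1.51-fold lower), while MUC1 rose 1.90-fold. FOXA1 (2.45 CPM in shControl and 0.97 CPM in shNSD3) and MUC1 (2.48 and 4.71 CPM) were low in both groups. The luminal list was called with DESeq2 size factors (0.0499), with upper-quartile factors (0.0482), without shControl replicate 2 (0.0226), without shNSD3 replicate 3 (0.0367) and by fry (0.00101), but not with positional centring (0.25). Of 13 basal genes 5 rose and 6 fell, or 5 and 7 adjusted over the list alone (camera adjusted p = 0.866, direction up, mean 0.11 but median -0.16). KRT17, a basal keratin gene, rose 3.32-fold, whereas CDH3 and LAMB3 fell 1.91-fold and 1.30-fold. Of 12 stem-cell associated genes 7 rose and 3 fell (camera adjusted p = 0.341), with PROCR 1.47-fold and ABCG2 1.39-fold higher and BMI1 1.35-fold lower, the last in a region where neighbouring genes had a median of -0.53. The luminal and stem-cell counts were the same adjusted over the list alone.

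Mitotic genes fell, by small amounts. Of 27 genes of G2 and mitosis, 23 fell and 0 rose, also adjusted over the list alone, with a median log2 fold change of -0.21 (camera adjusted p = 1.05e-07, or adjusted p = 0.294 with an estimated correlation). HMMR, a spindle-associated gene, fell 1.67-fold and the mitotic kinesin gene KIF20A 1.55-fold (323 ± 11.6 against 208 ± 5.82 CPM). The 4 that did not pass the test were CCNB1, PLK1, MKI67 and TOP2A. Genes of G1/S and DNA replication went both ways, 9 higher and 6 lower of 27, or 9 and 5 adjusted over the list alone (camera adjusted p = 0.341, fry adjusted p = 0.00904). FEN1 (1.44-fold higher) and TYMS (1.40-fold higher) lay in regions whose neighbouring genes had medians of 0.41 and 0.48. Nucleolar and MYC target genes fell more often than they rose, 17 against 3 of 26, also adjusted over the list alone (camera adjusted p = 0.0231, or adjusted p = 0.622 with an estimated correlation, and 0.103 with library totals). NPM1 fell 1.33-fold and NOP2 1.28-fold, where the neighbours of NOP2 had a median of -0.47. With positional centring NOP2 was called higher instead (0.11, adjusted p = 0.0114), a p-value that leaves out the error of the neighbours' median. PPAN rose 1.27-fold, a call lost without shNSD3 replicate 3 (adjusted p = 0.0516) and with positional centring, where the log2 fold change went from 0.35 to 0.14 (adjusted p = 0.264) and the neighbours had a median of 0.21.

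Interferon-stimulated genes rose. Of 29 genes 19 rose and 1, XAF1, fell (1.61-fold), also adjusted over the list alone, with a median log2 fold change of 0.52 (camera adjusted p = 1.69e-09, or adjusted p = 0.0638 with an estimated correlation). IFI27 rose 5.29-fold, from 1.69 ± 0.366 to 8.97 ± 0.809 CPM, and IFIT2 rose 3.00-fold, from 5.19 ± 0.115 to 15.5 ± 0.297 CPM. NF-kB target and cytokine genes rose more often than they fell, 14 against 5 of 22, also adjusted over the list alone (camera adjusted p = 0.00162, or adjusted p = 0.115 with an estimated correlation). CSF1, the macrophage colony-stimulating factor gene, rose 2.63-fold (45.1 ± 2.20 against 119 ± 0.741 CPM) and the apoptosis inhibitor gene BIRC3 rose 2.01-fold. The 5 that fell were IL1B (2.98-fold lower, 229 ± 8.60 against 76.9 ± 1.44 CPM), IL1A, CXCL8, CXCL1 and PTGS2.

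Genes of unfolded-protein and amino-acid stress fell, as did genes of hypoxia and glycolysis. Of 24 unfolded-protein and amino-acid stress genes 17 fell and 3 rose, also adjusted over the list alone, with a median log2 fold change of -0.50 (camera adjusted p = 2.85e-10, or adjusted p = 0.0638 with an estimated correlation). CHAC1, which encodes a glutathione-degrading enzyme, fell 2.67-fold and PHGDH, the gene of the first enzyme of serine synthesis, fell 2.13-fold (72.1 ± 3.28 against 33.9 ± 0.708 CPM). SEL1L, DNAJB9 and PDIA4 were the 3 that rose, SEL1L by 1.54-fold. Of 23 hypoxia and glycolysis genes 18 fell and 0 rose, also adjusted over the list alone, with a median of -0.37 (camera adjusted p = 1.40e-13, or adjusted p = 0.0638 with an estimated correlation). NDRG1 fell 2.01-fold (461 ± 13.6 against 229 ± 3.49 CPM) and BNIP3, a mitophagy gene, 1.75-fold. Sterol synthesis genes were mixed, 5 higher and 8 lower of 23, also adjusted over the list alone (camera adjusted p = 0.656). IDI1 fell 1.30-fold, among neighbours with a median of -0.43.

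Other lists showed no common direction in camera. Of 24 TGF-beta and YAP/TEAD target genes 8 rose and 10 fell (adjusted p = 0.866, direction up, median -0.03 and mean -0.02), with ID2 1.67-fold lower and TGFBI 1.41-fold lower. Of 20 p53 target genes 6 rose and 6 fell (adjusted p = 0.938), with GDF15 3.01-fold and PMAIP1 1.33-fold higher and SESN2 1.65-fold lower. GDF15 was low in both groups (1.18 CPM in shControl and 3.59 CPM in shNSD3). Of 15 immediate-early and heat-shock genes 7 rose and 3 fell (adjusted p = 0.442), with JUNB 1.58-fold and HSPA1B 1.41-fold higher and EGR1 1.81-fold lower. The EGR1 call was lost without the low-count filter (adjusted p = 0.0592), with positional centring (0.0838), without shControl replicate 2 (0.0590) and without shNSD3 replicate 1 (0.0544), 2 (0.0822) or 3 (0.0820). These counts were the same adjusted over the list alone.

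Most leukocyte genes were too low to be tested. Of 16 leukocyte genes 4 were tested, and CD14, CD68 (40.7 to 54.8 CPM) and CSF1R rose while CD8A fell, also adjusted over the list alone (camera adjusted p = 0.365). Of 8 endothelial and stromal genes 4 rose (CDH5, LUM, PDGFRB and COL1A1) and 2 fell (ESAM and RGS5), also adjusted over the list alone (camera adjusted p = 0.341). The endothelial cadherin gene CDH5 rose from 0.144 to 2.03 CPM. Replication-dependent histone genes, whose transcripts are poorly captured by poly(A) selection, rose in 4 cases (HIST1H1C, HIST1H2AC, HIST1H2BD and HIST1H2BK) and fell in 1 (HIST1H4C) of 10, also adjusted over the list alone (camera adjusted p = 0.0268, or adjusted p = 0.188 with an estimated correlation, and 0.0621 with library totals). The histone list was not called without shControl replicate 3 (0.0641), with limma-voom before camera (0.0718), with cameraPR (0.0679) or with positional centring (0.0970).

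**Figure D2:**
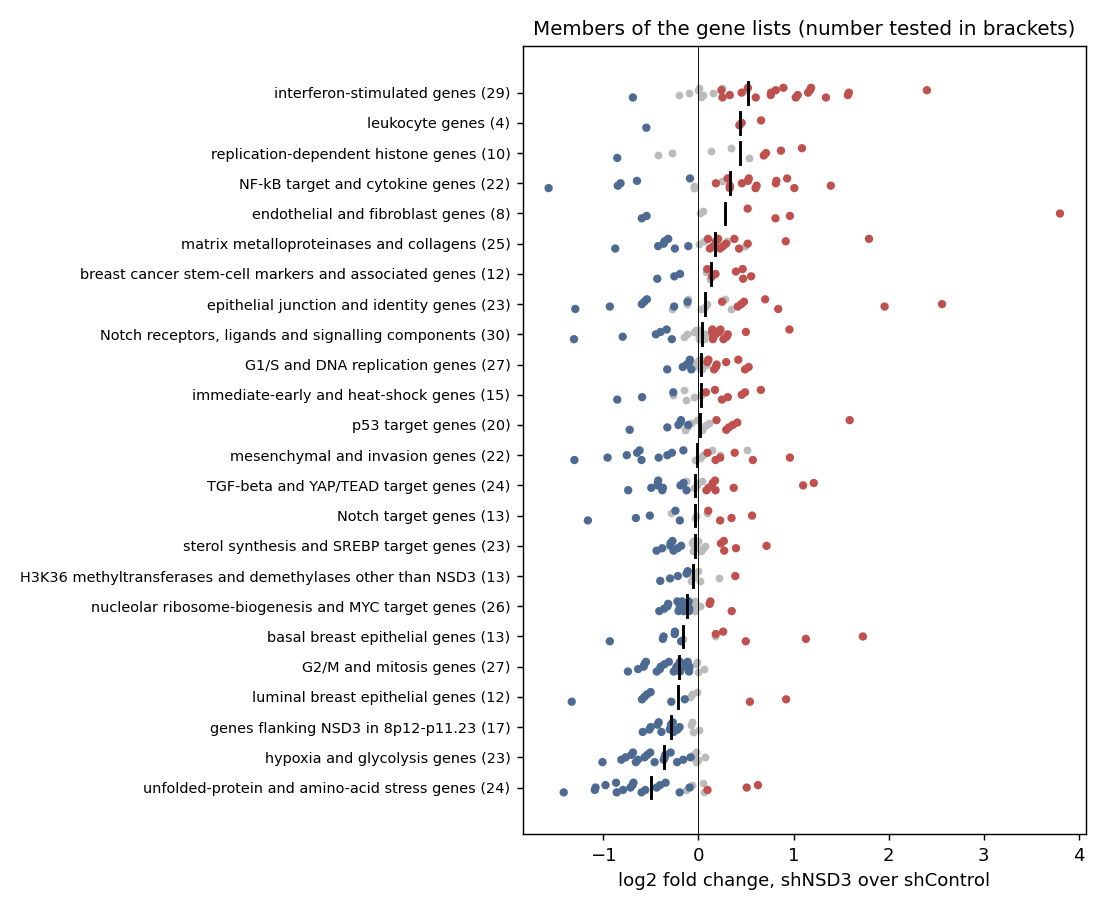
Log2 fold change of each tested list member (points, horizontal axis), red for called higher, blue for called lower and grey for not called, with the list median as a black bar. Unfolded-protein and amino-acid stress genes had the lowest median (-0.50) and interferon-stimulated genes the highest (0.52).

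Fold changes followed chromosomal position. On chromosomes 12 and 15, 87.5% and 88.3% of genes with at least 5 CPM were lower in shNSD3, each with a median log2 fold change of -0.27, whereas 74.3% of such genes on chromosome 16 were higher. Of 528 blocks of 20 neighbouring genes, 57 had a median under -0.25 and 32 a median over 0.25, where single blocks reached 0.331 in absolute value in 100 shuffles of gene order. The lowest block ran from HACD1 to APBB1IP on chromosome 10 (median -0.54, 18 of 20 genes called lower and 0 higher) and the highest from USP14 to LAMA1 on chromosome 18 (median 0.48, 19 of 20 called higher). The SD of block medians was 0.175, against at most 0.0776 in 100 such shuffles. After the neighbours' median was subtracted, 7556 genes were called, and 5925 of the 8756 called genes that could be placed were still called in the same direction. The calls after centring take that median as known.

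**Figure D3:**
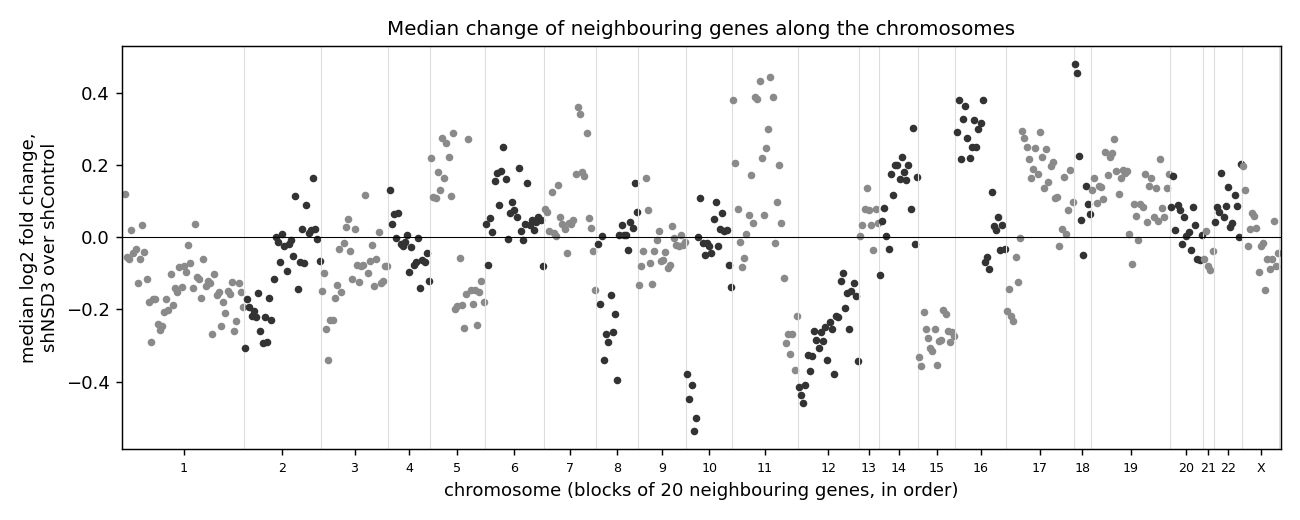
Median log2 fold change of blocks of 20 neighbouring genes (points, vertical axis) in chromosomal order, with shading alternating by chromosome. Blocks of chromosomes 12 and 15 lie below 0, and runs of blocks share a level, as on the first part of chromosomes 10 (lower) and 18 (higher).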

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

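Positional centring and cameraPR were chosen after seeing the data; the other alternatives were fixed beforehand. NSD3 stayed lower throughout, with log2 fold changes from -2.25 to -2.01. Over 16 alternatives the number of called genes ran from 7556 to 9155 (DESeq2 7643, limma-voom 8821, leave-one-out 8102 to 8758), and the number changed at least 2-fold from 394 (filter at 1 CPM, which removes low genes) to 938 (no filter), with 669 to 745 when a library was left out. Calls with library totals were 5960 higher and 3195 lower. Replicate numbers did not pair the libraries: the correlations of same-numbered deviations were -0.029, -0.015 and 0.032, and only shControl replicate 3 correlated best with the shNSD3 library of its own number. With the number as a block 9064 genes were called, the mesenchymal list lost its call (camera adjusted p = 0.0881) and the luminal list stayed uncalled (0.0637). Of 790 named-gene values outside leave-one-out, 770 kept direction and side of the threshold, 12 kept direction but lost the call, 2 gained it and 6 changed sign. Of 474 leave-one-out values 464 kept both. The sign changes were NSD2 with library totals (0.029), NOTCH1 without shControl replicate 2 (-0.082) or shNSD3 replicate 3 (-0.011, but up to 0.10 in the other fits) and, with positional centring, NSD1 (0.0022), KDM2A (-0.027), NOP2 (0.11), IDI1 (0.046) and BMI1 (0.093); apart from centring, whose construction removes a regional shift, the cause was not tested. Among the sign changes with centring, NSD1, KDM2A, IDI1 and BMI1 also lost their calls (adjusted p = 0.964, 0.4745, 0.371 and 0.410). NOP2 went from called lower to called higher (adjusted p = 0.0114), with the neighbours' median taken as known. Calls lost with centring without a sign change included JAG1 (adjusted p = 0.0585), HES1 (0.0622), HEYL (0.154), IGF1R (0.719), KDM4A (0.183), TYMS (0.753), PPAN (0.264) and EGR1 (0.0838).

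Among lists, adjusted p-values follow. The Notch target list, not called anywhere, turned to down with upper-quartile factors (0.998), library totals (0.968), no filter (0.958), the block (0.998), fry (0.660), limma-voom (0.952), cameraPR (0.961) and without shControl replicate 1 (0.949) or 2 (0.977) or shNSD3 replicate 1 (0.926), though not in the other 3 leave-one-out fits (0.867 to 0.981). The TGF-beta and YAP list turned with no filter (0.734), the block (0.857), limma-voom (0.738) and cameraPR (0.732), the basal list with the block (0.998), limma-voom (0.892), cameraPR (0.955), and centring (0.978), the p53 list with fry (0.975), and the G1/S list with centring (0.992). The basal, p53 and matrix lists also turned without shControl replicate 2 (0.977 each) but in no other leave-one-out fit (lowest 0.694, 0.845 and 0.747). The mesenchymal call was lost with no filter (0.114), an estimated correlation (0.143), limma-voom (0.317) and cameraPR (0.302), and turned to up with centring (0.996). The G2 and mitosis call was lost with an estimated correlation (0.294), as were all 9 list calls. Of 18 lists called by fry, those not called by camera included Notch components (0.0189), G1/S (0.00904), H3K36 enzymes (2.66e-04), sterol synthesis (0.0391), stem-cell (0.00528), luminal (0.00101), leukocyte (4.06e-04), endothelial and stromal (0.00151) and immediate-early genes (0.0473). The cause was not tested. Without the estimated correlation, the interferon, NF-kB, stress, hypoxia and mitosis lists stayed called, at adjusted p-values of at most 0.00318. Depth limits genes near 1 CPM, where 1 library holds about 30 counts.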

Other observations

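The tests of MIR30A reads and of leukocyte genes, both gene groups of the next paragraph and positional centring were chosen only after the values had been seen.

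X-linked cancer-testis genes, normally silent outside the germ line, changed in both directions. Of 117 such genes with a count entry, 13 passed the expression filter, and of these 9 rose and 4 fell, each by at least 2-fold. Genes near 0 in a group, such as PASD1 and MAGEA3 in shControl and CSAG4 in shNSD3, passed the filter only through the other group. A 2-fold change in such genes was thus largely set by the filter. Over all 14987 genes tested, 648 changed at least 2-fold. PASD1, MAGEA3, MAGEA10 and VCX3A had at most 1 count over the shControl libraries, MAGEB1 rose from 0.119 to 4.42 CPM and MAGEB2 from 2.00 to 13.2 CPM. MAGEA12, CSAG1, CSAG4 and CT83 fell, MAGEA12 from 18.1 ± 0.198 to 6.18 ± 0.348 CPM (SD, n = 3), although MAGEA12 and CSAG1 neighbour MAGEA3 and MAGEA6 on the chromosome. Counted over all genes, 6 had at most 3 counts over the shControl libraries and at least 100 over the shNSD3 libraries (MIR30A, PASD1, MAGEA3, CSMD1, LINC00668 and VCX3A), and 0 the reverse. MHC class II genes, which present antigen and are usually restricted to immune cells, also rose, 10 of 11 tested with a median log2 fold change of 1.25. CD74, the invariant chain gene, rose from 7.20 ± 0.215 to 68.0 ± 1.29 CPM, HLA-DRA from 7.87 ± 0.279 to 28.8 ± 0.217 CPM and their regulator CIITA from 4.02 ± 0.565 to 8.60 ± 0.210 CPM. HLA-DOB did not pass the test (0.46 ± 0.22, edgeR adjusted p = 0.0895).

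The first pattern weighed is the shift of neighbouring genes. A GC content or transcript length bias is argued against, since after a correction for both (values for 96.5% of genes) the SD of block medians was 0.163, above the highest of 100 shuffles (0.0748). Copy number differences between the infected populations and an effect of NSD3 loss on whole regions both stay open, because the sources do not say that a group holds more than 1 infected population. Over 256 blocks of 40 genes, the medians of the more and the less expressed genes correlated at 0.889 with a slope of 0.914, but blocks already seen to differ would give such a correlation under either explanation, so it does not decide. On some chromosomes the block medians held a level over long runs and then stepped between adjacent blocks. The step was from -0.501 to 0 on chromosome 10 (after KIF5B), from 0.38 to -0.07 on chromosome 16 (after VPS35) and from 0.289 to -0.198 on chromosome 5 (after NUDT12). Copy number differences over chromosome parts would give such runs and steps. The steps were not tested against a regional effect of NSD3 loss, and no DNA measurement was analysed here.

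The second pattern is the 77345 counts of MIR30A in the shNSD3 libraries. Transcription of MIR30A as part of LINC00472, the annotated host transcript, is argued against, since LINC00472 had a log2 fold change of 0.06 ± 0.04 (SE). The more distant RIMS1 (0.85 ± 0.19), FAM135A (0.44 ± 0.05) and SMAP1 (0.39 ± 0.04) rose by less than 2-fold. OGFRL1 fell slightly (-0.11 ± 0.04), and MIR30C2 of the same locus held 27 counts in shControl and 30 in shNSD3. Hairpins of this vector type sit in a scaffold taken from human MIR30A, so reads of the vector's miR-30 hairpin scaffold may be the source, and transcription of MIR30A from a start of its own stays open too. The paralogs MIR30B, MIR30C1, MIR30D and MIR30E held 2 counts in either group, which does not decide between the scaffold and such a start. Whether the control vector carried the scaffold, which had 0 counts there, is not given in the sources used here.

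The third pattern is the rise of MHC class II genes. Leukocytes among the cells are argued against, since PTPRC, abundant in all leukocytes, reached at most 0.102 CPM in the shNSD3 libraries while CD74 was at 68.7 CPM or more by library totals, and TYROBP had 0 counts in all libraries. CD14 (0.66 ± 0.16), CSF1R (0.45 ± 0.10) and CD68 (0.43 ± 0.04) did rise, by less than 2-fold (log2, SE). A shift of the chromosomal region is argued against too, since the class II HLA genes exceeded the median of 50 flanking genes by 1.06 on the log2 scale. A response of these cells to NSD3 loss, or a difference between the infected populations, may account for the rise, and these data hold no test between them.

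With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 8861 called genes, 648 of them at least 2-fold. Each of the other 9 splits gave 0 by edgeR, with 143 genes at an unadjusted p under 0.05 in the highest of them. Each of these 9 splits mixes the groups, so the group difference widens its residual spread. Their 0 calls therefore do not measure how many calls would arise without a group difference. Other tools were not run on the splits. For called lists the real split gave 9 and the other splits 3 to 6. Camera at the preset correlation thus called lists in splits where edgeR called no gene. Its adjusted p-values are to be read with that caution. In each case 1 of the 10 splits, the real one, reached the real value.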
